A study of Mus musculus with 8 samples.

How the data were processed

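Dorsal skin of wild-type mouse embryos was profiled on 8 Affymetrix Mouse Genome 430 2.0 arrays, with 2 arrays at embryonic day 14.5 (E14.5), 3 at E16.5 and 3 at E18.5. The array type comes from the probe table supplied with the values, and the stage of each array from its age label. Replicate numbers were given in accession order and pair no arrays across stages. The sample titles carry number codes whose meaning is not given in the sources used here, so some arrays may share a litter.

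The deposited value for each of the 45101 probesets and each array is a signal intensity on a linear scale. Per the submitters' processing notes the tools were Affymetrix Expression Console 1.1 and PLIER 2.0, with no role or order given. The background correction and the normalization between arrays are not given in the sources used here, nor is whether the E14.5 arrays were summarised together with the others, whose signals are distributed differently. Per the labels' protocols, total RNA was extracted with Trizol, amplified from random hexamers and hybridised as biotin-labelled single-stranded DNA in the sense orientation. That protocol is given for all 8 arrays, but it is one for whole-transcript arrays and the array is a 3′ expression array, so how the targets were made is uncertain. Both limits bear on every difference from E14.5.

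Of the probesets, 34958 carried 1 gene symbol, 932 carried several and 9211 carried none here. Gene IDs of 34754 probesets were found in a reference table of mouse genes (assembly GRCm38.p6), and 0 symbols needed updating. Control probesets (64) and probesets with several or no symbols were left out of the gene tests, which left 34945. For a gene with more than 1 probeset, the probeset with the highest mean over the 8 arrays was used, giving 18193 genes, of which 9010 had 2 or more probesets. No coordinates were used. Genes with near-identical copies, such as the Lce, Sprr2 and Krtap families, share probe sequence, so their separate values are uncertain.

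Signals were analysed as log2(signal + 16) with no further normalization between arrays. The limma package (version 3.58.1, R 4.3.3) fitted one mean per stage to all 8 arrays (lmFit, then eBayes with a variance trend), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were E16.5 against E14.5, E18.5 against E16.5, E18.5 against E14.5 and the second change minus the first. A moderated F test covered all 3 stages. Every adjusted p for a gene is from limma. Changes are given as log2 differences with their standard error (SE), and signals as mean ± SD over the arrays of a stage. The number of arrays limits the precision.

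Background was set per array at the 95th percentile of 80 probesets of olfactory and vomeronasal receptor genes, which skin is not expected to express. Where any array of the dimmer stage lay at or below it, the fold is given as at least the brighter stage's mean over the higher of the background and the dim signal, averaged over arrays on the log2 scale. A log2 change beside such a fold, or of the same gene without an array, is that of the measured signals. For the second change minus the first, a signal at or below background was taken as anywhere from 0 to background.

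A total of 34 gene lists covering epidermal layers, hair follicle, dermis, other cell types and general programmes were written before the data were examined, together with the tests and the other settings to be tried. Each list of 5 or more measured genes was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists, then with an estimated correlation. fry, which asks whether a list's genes move on balance in one direction, was an alternative. Members are counted over all genes tested and again with p-values adjusted over the list alone.

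Genes were named by a rule set in advance. It took the 5 largest rises and 5 largest falls of each contrast, among called genes whose arrays did not overlap and whose higher stage mean lay above background. It also took the 2 members of each called list that moved furthest in its direction in each interval, 12 epidermal stage genes, 3 genes of each pattern over both intervals and 3 genes in each direction with the most unequal changes. Symbols that are only clone or accession numbers were counted and not named, which passed over 2 falls from E16.5 to E18.5. Other genes named as examples of a list were chosen after their values were seen.

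Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, filters on dim genes, other variance settings, array weights, the mean of all probesets of a gene, a fold threshold of 2, only the arrays of the stages compared, each array left out in turn and genes of other tissues left out. The median of all probesets, and only genes whose 2 or more probesets moved together, were added after the data were seen.

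The tests were checked on simulated data for 18193 genes drawn with the real means and spreads. For E18.5 against E16.5, 28 of 100 genes with an added log2 change of 1 and 84 of 100 with 2 were recovered, with 8 false calls. For E16.5 against E14.5 the numbers were 22 and 79 of 100, with 5 false calls. No other genes were changed, so the calls in all were 120 and 106, against 2340 and 10526 in the real data. With so few changed genes the Benjamini-Hochberg cutoff was stricter than in the real data. These shares therefore do not give the recovery in the real comparisons. A simulated list shifted by 1 was called in both, and 0 of the other lists were. Genes were drawn independently of each other, so this check does not cover false list calls from correlation among the genes of a list.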

Results

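Gene expression was measured in mouse dorsal skin at 3 embryonic stages, in a series designed to follow gene regulation while the epidermis differentiates. There were 2 arrays at E14.5, 3 at E16.5 and 3 at E18.5. Between 12186 and 13828 of the 18193 genes per array gave signals above background. The labels do not state that the samples came from separate animals, so the p-values measure the spread between these samples. Xist, expressed in females, gave 10700 and 26.1 at E14.5, 82.4 to 11736 at E16.5 and 193 to 13611 at E18.5. These values argue against a purely technical spread within a stage, but some arrays may still share an animal.

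Arrays of one stage correlated across genes with r of 0.961 at E14.5, 0.986 to 0.989 at E16.5 and 0.962 to 0.967 at E18.5. Between E16.5 and E18.5 r was 0.950 to 0.963, and between E14.5 and the later stages 0.792 to 0.832. The first principal component held 71.3% of the variance and set the E14.5 arrays apart, and the second, with 11.98%, separated E16.5 from E18.5.

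The E14.5 arrays also differed in their control probesets. The 3′ over 5′ signal ratio of beta-actin was 6.50 and 6.91 at E14.5 against 1.11 to 1.37 on the other 6 arrays, and that of Gapdh was 2.96 and 3.03 against 0.692 to 0.869. The hybridisation control bioB gave 5592 and 5287 at E14.5 and 539.6 to 648.6 elsewhere. The middle probeset of 18S ribosomal RNA gave 10133 and 8729 against 117 to 211, and the median signal of all probesets was 63.4 and 60.8 against 120.1 to 153. Stage and array preparation therefore cannot be separated in any comparison with E14.5, and the comparison of E18.5 with E16.5 is given first. Those stages also differed in controls without overlap, by less. The beta-actin ratio was 1.11 to 1.14 at E16.5 and 1.35 to 1.37 at E18.5, and the hybridisation control cre gave 17832 to 19152 and 25316 to 26636, so an effect of array handling is not excluded there either.

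**Figure D1:**
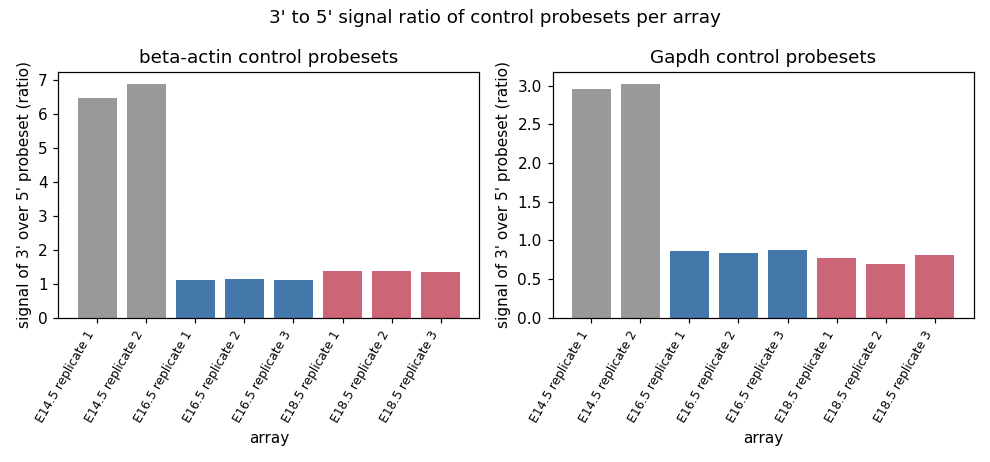
Bars give, for each of the 8 arrays, the ratio of the signal of the 3′ control probeset to that of the 5′ control probeset of beta-actin (left) and Gapdh (right), on axes that start at 0. Both E14.5 arrays stand above the other 6 in both genes, at 6.50 and 6.91 for beta-actin and 2.96 and 3.03 for Gapdh.

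Between E16.5 and E18.5, hair follicle keratins and an adipocyte gene were among the largest rises. Krt25, an inner root sheath keratin, rose at least 88.6-fold, from a background-level signal of 7.86 ± 3.93 to 6292 ± 4586 (SD, n = 3 each; log2 change 7.77 ± 0.53 SE, adjusted p = 0.000119). Krt71, another inner root sheath keratin, was at least 53.2-fold higher (log2 6.27 ± 0.51, adjusted p = 0.000269). Adipoq, which encodes adiponectin, was at least 48.4-fold higher (log2 5.85 ± 0.75, adjusted p = 0.00178). The milk casein genes Csn1s2a (at least 38.3-fold, adjusted p = 0.00603) and Csn2 (at least 29.3-fold, adjusted p = 0.00931) were also among the 5 largest rises, with E18.5 signals of 6130 ± 8358 and 4310 ± 5511 (SD, n = 3). Without E18.5 replicate 2 their log2 changes went from 6.42 to 5.01 and from 5.81 to 4.49, and without replicate 3 to 7.89 and 7.30. The log2 change of Krt25 was 8.36 without E18.5 replicate 3, that of Krt71 5.68 without E18.5 replicate 1, and that of Adipoq 6.86 and 5.19 without E16.5 replicates 1 and 3. The call of Csn1s2a was lost with the median of its 5 probesets (adjusted p = 0.0881).

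The 5 largest falls that carried a gene name were as follows. Krtap13, a keratin-associated protein gene, fell at least 64.7-fold (log2 −8.09 ± 0.45 SE, n = 3 each, adjusted p = 4.84e-05). Lce3f, a late cornified envelope gene, fell at least 31.7-fold (log2 −6.46 ± 0.44, adjusted p = 0.000119). Both belong to families of similar sequence. Krt77, a type II keratin, went from 20700 ± 412 to 545 ± 194, a 38.7-fold difference (log2 −5.28 ± 0.23, adjusted p = 1.01e-05). Sprr1b, a cornified envelope precursor, was 20.8-fold lower, and Saa1, an acute phase protein gene, at least 7.06-fold lower.

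Of the 34 hair shaft and inner root sheath genes measured, 18 rose, 1 fell and 15 did not pass the test (adjusted over the list alone, 23 and 1), with a median log2 change of 1.79 against 0.12 for all genes. The camera test gave adjusted p = 5e-09, and adjusted p = 0.618 with an estimated correlation. Krt27 (at least 30.9-fold, log2 5.79 ± 0.61 SE, n = 3 each), Krt28 (at least 27.9-fold), Krt73 (at least 29.3-fold), Krt35 (at least 18.7-fold) and Tchh, which encodes trichohyalin (at least 26.6-fold, log2 4.76 ± 0.46), were among the rises, with Tchh at log2 5.35 without E18.5 replicate 3. In the hair placode and follicle signalling list 11 of 34 rose and 1 fell (adjusted over the list alone, 17 and 2), with a median of 0.41 (camera adjusted p = 0.00933, and adjusted p = 0.618 with an estimated correlation). Its members Lhx2 (3.82-fold), Hoxc13 (3.65-fold) and Shh, the Sonic hedgehog ligand (log2 1.53 ± 0.19), rose, although Lhx2 was not called without E16.5 replicate 3 (adjusted p = 0.0517) or with a pseudocount of 1 (adjusted p = 0.0859), and Axin2, a Wnt target, fell by 0.72 ± 0.15 on the log2 scale. Keratin-associated protein genes rose in 8 of 38 and fell in 1, which was Krtap13 (adjusted over the list alone, 13 and 1; median 0.93; camera adjusted p = 0.000945, and adjusted p = 0.618 with an estimated correlation). Krtap17-1 was at least 4.59-fold higher, and Krtap8-1 at least 3.29-fold higher. The call of Krtap8-1 was lost without any 1 of E16.5 replicates 1, 2 and 3 and E18.5 replicates 1 and 2 (adjusted p = 0.0641 to 0.122; log2 1.61 without E18.5 replicate 1 and 3.05 without replicate 3), and the list call was lost among genes above background on 2 arrays (adjusted p = 0.22). With the median of all probesets of a gene the follicle signalling list was not called (adjusted p = 0.0544).

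Of 27 adipocyte genes, 15 rose and 2 fell (adjusted over the list alone, 16 and 2), with a median log2 change of 1.02 (camera adjusted p = 1.51e-06, and adjusted p = 0.618 with an estimated correlation). Retn, which encodes resistin, was at least 13.1-fold higher. Cidec (at least 4.59-fold), Car3 (log2 2.90 ± 0.26 SE, n = 3 each), Fabp4 (1.77 ± 0.10) and Lpl (1.51 ± 0.21) rose, and Dgat2 (−1.09 ± 0.14) and Cebpa (−0.63 ± 0.16) fell. One E16.5 array had an Adipoq signal of 351, against 39.6 and 20.6 on the others of that stage.

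Melanocyte genes rose in 9 of 17 and fell in 2 (adjusted over the list alone, 10 and 2; median log2 0.88; camera adjusted p = 0.00894, and adjusted p = 0.618 with an estimated correlation). The pigment enzyme genes Tyrp1 (6.00-fold, log2 2.59 ± 0.28 SE, n = 3 each) and Dct (3.10-fold, 1.63 ± 0.26) rose, and Kit and Rab38 fell. Macrophage, dendritic and Langerhans cell genes rose in 5 of 33 and fell in 1 (adjusted over the list alone, 11 and 1; median 0.43; camera adjusted p = 0.00649, and adjusted p = 0.618 with an estimated correlation). Among them C1qb, a complement gene, was 4.24-fold higher (2.08 ± 0.20), Cd163 2.47-fold higher, and Cx3cr1 fell (−1.08 ± 0.27). Of 43 ribosomal protein genes 26 rose and 1, Rpl27a, fell (adjusted over the list alone, 31 and 1), with a median of 0.42 (camera adjusted p = 1.4e-10, and adjusted p = 0.618 with an estimated correlation). Rps20 was 1.91-fold higher (0.93 ± 0.11), but its call was lost with the mean or the median of its 4 probesets (adjusted p up to 0.106). Rpl3l, a paralogue expressed in muscle, was at least 3.22-fold higher. The melanocyte list was not called among genes above the median gene, nor the melanocyte and macrophage lists among genes with agreeing probesets (adjusted p up to 0.383 and 0.25). Under quantile normalization the ribosomal list was not called, with a median of 0.08 (adjusted p = 0.123).

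In the dermal fibroblast and extracellular matrix list 12 of 40 genes rose and 1 fell (adjusted over the list alone, 13 and 1; median log2 0.24; camera adjusted p = 0.024, and adjusted p = 0.618 with an estimated correlation), and fry gave adjusted p = 0.106. Fbln5 was 2.18-fold higher and Loxl1 1.73-fold higher, both needed for elastic fibres. The list's call was lost under quantile normalization, where its median was −0.01 (adjusted p = 0.495), under median centring (adjusted p = 0.0878), without a variance trend (adjusted p = 0.0851), with the mean or median of probesets (adjusted p = 0.309 and 0.246), among agreeing probesets (adjusted p = 0.0827), without E16.5 replicate 2 (adjusted p = 0.0606) and without E18.5 replicate 3 (adjusted p = 0.471). The call of Fbln5 was lost with the mean or median of its probesets (adjusted p = 0.158 and 0.171), and that of Loxl1 with that mean too (adjusted p = 0.0689) and without E16.5 replicate 2 or 3 (adjusted p = 0.086 and 0.0941).

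Genes of the epidermal lipid barrier were set lower than other genes by camera. Of 36 measured, 13 fell, 3 rose and 20 did not pass the test (adjusted over the list alone, 19 fell and 4 rose), with a median log2 change of −0.63. The camera test gave adjusted p = 5.35e-08, and adjusted p = 0.618 with an estimated correlation; fry gave adjusted p = 0.106. Sptlc3, a subunit of the enzyme that starts sphingolipid synthesis, was 3.42-fold lower (log2 −1.78 ± 0.21 SE, n = 3 each). Alox12b, the lipoxygenase of the cornified lipid envelope, was 3.21-fold lower (−1.68 ± 0.37), and was not called without E16.5 replicate 2, E16.5 replicate 3 or E18.5 replicate 1 (adjusted p = 0.063, 0.0731 and 0.0609). Elovl6 (−1.11 ± 0.11) and Sult2b1 (−1.35 ± 0.21) fell too. The 3 members that rose were Degs2 (at least 4.35-fold), Elovl3 (at least 5.21-fold) and Fa2h (log2 2.12 ± 0.38). The cholesterol synthesis list had 4 falls, 0 rises and a median of −0.11 among 20 genes (adjusted over the list alone, 6 falls; camera adjusted p = 0.01, and adjusted p = 0.618 with an estimated correlation), and fry gave adjusted p = 0.311. Dhcr7 was 2.19-fold lower and Sqle 1.90-fold lower, and the list's call was lost without E18.5 replicate 3 (adjusted p = 0.189), under quantile normalization (adjusted p = 0.0798), with the mean or median of probesets (adjusted p = 0.108 and 0.164) and with either filter on dim genes (adjusted p = 0.295 and 0.0586).

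Cornified envelope and granular layer genes went both ways, with 6 of 45 rising and 13 falling (adjusted over the list alone, 10 and 13), a median log2 change of 0.01 and a mean of −0.14, and the list was not called (camera adjusted p = 0.0994). Ivl, which encodes involucrin, fell by 1.05 ± 0.20 on the log2 scale (SE, n = 3 each, adjusted p = 0.00834), and so did Tgm1 (−1.02 ± 0.20), the crosslinking transglutaminase, and Sprr3 (at least 2.43-fold). Flg, which encodes filaggrin, rose 3.77-fold (1.91 ± 0.42, adjusted p = 0.0169), but not without E16.5 replicate 3, E18.5 replicate 1 or E18.5 replicate 2 (adjusted p = 0.0627, 0.0565 and 0.0517). Grhl3, a barrier transcription factor, was 3.47-fold lower (adjusted p = 0.00144). Trp63, the master regulator of stratified epithelium, rose 1.72-fold (adjusted p = 0.0133), a call lost without E16.5 replicate 1 or 3 (adjusted p = 0.0559 and 0.0652) and with the mean or median of its 4 probesets (adjusted p up to 0.402). Krt1 had a log2 change of 0.54 ± 0.16 (adjusted p = 0.0488), a call lost in 12 of its 21 alternatives, among them each array of either stage left out. No call was made for Krt5 (0.24 ± 0.12, adjusted p = 0.235), Krt14 (0.26 ± 0.11, adjusted p = 0.155), Krt10 (0.40 ± 0.12, adjusted p = 0.054, but called in 7 alternatives with adjusted p from 0.0195 to 0.0332; at or near the top of the signal range of each array of both stages, where a change may not show), Lor (0.26 ± 0.15, adjusted p = 0.27), Klf4 (0.05 ± 0.22, adjusted p = 0.908), Krt8 (−0.63 ± 0.45, adjusted p = 0.388) or Krt18 (0.49 ± 0.65, adjusted p = 0.649).

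A further 6 lists were called lower than other genes by camera, with few called members, and fry called none of them. These were periderm and simple epithelium (5 of 17 fell, 1 rose; adjusted p = 0.0446), epidermal proteases and inhibitors (2 of 31 fell; adjusted p = 0.0411), erythroid and blood (4 of 20 fell; adjusted p = 0.0475), mast cell (3 of 18 fell, 1 rose; adjusted p = 0.00894), proliferation (6 of 52 fell; adjusted p = 0.00933) and fetal growth, imprinted and let-7 target genes (5 of 25 fell, 1 rose; adjusted p = 0.00677). Adjusted over the list alone, the falls were 6, 2, 4, 4, 6 and 6. In the same order the median log2 changes were −0.15, −0.16, −0.19, −0.44, −0.09 and −0.26, and fry gave adjusted p = 0.369, 0.499, 0.333, 0.239, 0.0595 and 0.21. The proteases gave adjusted p = 0.641 with an estimated correlation and the other 5 lists adjusted p = 0.618 with an estimated correlation. The members that fell included Krt13 (at least 4.71-fold) and Krt6a (3.48-fold), Klk13 (2.47-fold) and Tmprss13 (2.13-fold), the embryonic globin Hbb-y (at least 3.51-fold) and the red cell anion exchanger Slc4a1 (3.44-fold), Kit (1.61-fold), the mitotic kinase Bub1 (1.93-fold) and Ccne1 (1.68-fold), and Hmga2 (2.54-fold) and Igf2bp1 (1.85-fold), both let-7 targets. Mcpt2, a mast cell protease, had a log2 change of −1.30 ± 0.31 with its E18.5 signal at background.

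Leaving out 1 array ended several of these calls. The periderm list was lost in 5 such fits, and without E18.5 replicate 3 its median was 0.12 (adjusted p = 0.341). The erythroid list was lost in 6 such fits (adjusted p up to 0.119), the proteases in 4 (up to 0.471) and the mast cell list without E18.5 replicate 1 (adjusted p = 0.15). Filters on dim genes, scaling or the choice of probesets also ended the calls of the periderm, erythroid, proteases, proliferation (adjusted p up to 0.335), mast cell and fetal growth (adjusted p = 0.295) lists. Single genes lost without some arrays of the E16.5 or E18.5 stage were Krt13 (adjusted p up to 0.061), Krt6a (up to 0.0886), Tmprss13 (0.0627), Hbb-y (up to 0.123), Bub1 (up to 0.134), Ccne1 (up to 0.0914), Mcpt2 (up to 0.0947) and Igf2bp1 (up to 0.0634). Hbb-y was also lost without either E14.5 array, and its log2 change of −2.35 was −1.63 and −3.02 without E16.5 replicates 1 and 2. With the median of all probesets Krt13 (adjusted p = 0.13), Kit (adjusted p = 0.0982) and Bub1 (adjusted p = 0.393) were not called.

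In all, limma called 2340 of 18193 genes (12.9%) between E16.5 and E18.5. Of these, 1325 rose and 1015 fell, and 930 changed at least 2-fold. The count was 987, 1005 and 758 without E16.5 replicates 1, 2 and 3. The share that rose was 56.6%, and 36.2% under median centring, which moved the median change of all genes from 0.12 to 0.01. Among 498 genes with at least 2 called probesets, 83 had probesets called in opposite directions.

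**Figure D2:**
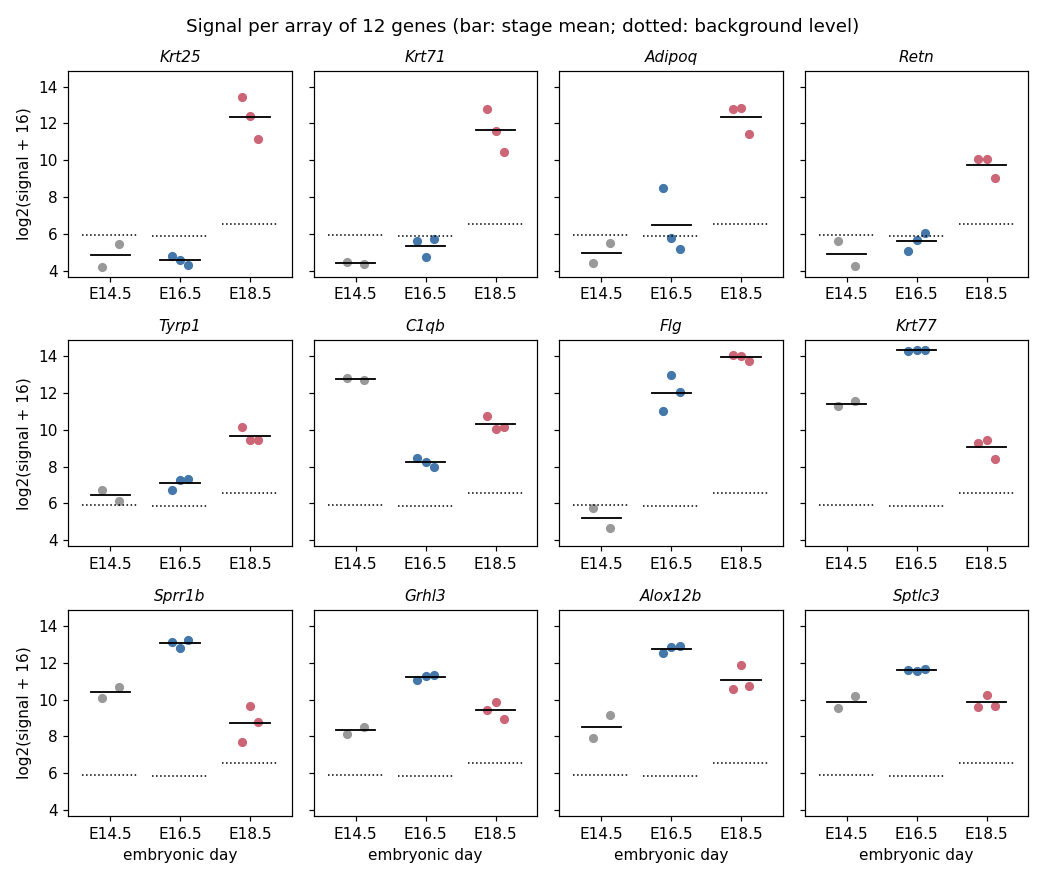
Each point is the log2(signal + 16) of 1 gene on 1 array, by embryonic stage (2, 3 and 3 arrays), with a bar at the stage mean and a dotted line at the mean background level of the stage. Krt25, Krt71 and Retn lie near background until E18.5, while Krt77, Sprr1b, Grhl3, Alox12b and Sptlc3 are highest at E16.5.

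**Figure D3:**
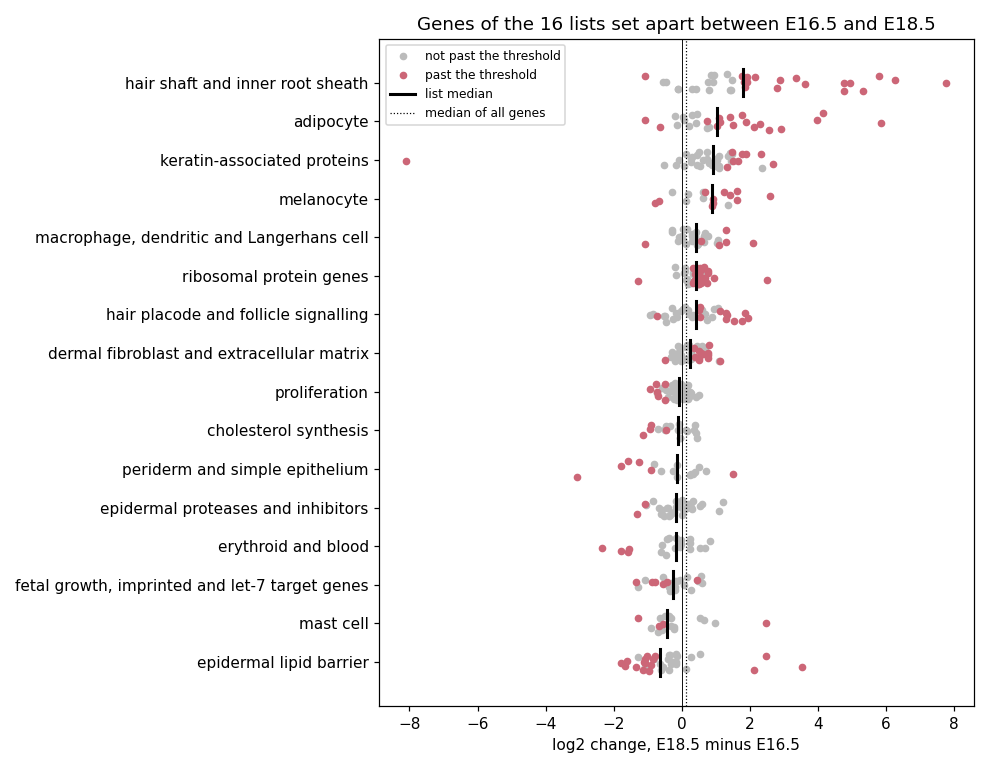
Points are the log2 changes from E16.5 to E18.5 of the measured genes of the 16 lists called by camera, in red where limma's adjusted p is under 0.05, with a black bar at each list's median, and a dotted line at the median of all genes, 0.12. The hair shaft and inner root sheath list lies highest (median 1.79) and the epidermal lipid barrier list lowest (median −0.63).

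Between E14.5 and E16.5, cornified envelope and granular layer genes were the group with the largest rise. Of 45 measured, 39 rose and 0 fell (adjusted over the list alone, 39 and 1), with a median log2 change of 3.05 against 0.30 for all genes (camera adjusted p = 4.3e-09, and adjusted p = 0.988 with an estimated correlation). Klk7, a protease of corneocyte shedding, rose at least 135-fold, from 4.22 ± 0.60 (n = 2) to 8376 ± 2148 (n = 3; log2 8.66 ± 0.24 SE, adjusted p = 1.9e-08). The late cornified envelope genes Lce1m, Lce1a1, Lce1i and Lce1c rose at least 132, 120, 120 and 112-fold, with values that near-identical copies may share. Flg rose at least 68.8-fold (log2 6.83 ± 0.47, adjusted p = 7.7e-07) and Ivl 48.9-fold (5.61 ± 0.22, adjusted p = 4.76e-08).

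Epidermal proteases and inhibitors rose in 27 of 31 genes and fell in 1 (adjusted over the list alone, 28 and 1; median log2 1.85; camera adjusted p = 2.12e-05, and adjusted p = 0.988 with an estimated correlation), among them Klk5 (38.9-fold; 5.28 ± 0.27 SE, n = 2 and 3). Epidermal lipid barrier genes rose in 24 of 36 and fell in 4, with the same counts adjusted over the list alone (median 1.34; camera adjusted p = 0.0211, and adjusted p = 0.988 with an estimated correlation), and the lipoxygenase genes Aloxe3 and Alox12b were at least 22.3-fold and 18.6-fold higher (log2 4.71 and 4.22; 4.04 and 3.58 without E14.5 replicate 1, 5.38 and 4.86 without replicate 2). The lipid barrier call was lost without E14.5 replicate 1 (median 0.99, adjusted p = 0.0802) and with either filter on dim genes (adjusted p up to 0.365 over all alternatives). Basal keratinocyte genes rose in 15 of 19 and fell in 2, with the same counts adjusted over the list alone (median 1.65; camera adjusted p = 0.0051, and adjusted p = 0.988 with an estimated correlation). Col17a1, a hemidesmosome collagen, was 14.5-fold higher and Sfn 8.97-fold higher.

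Skeletal muscle genes also rose, in 33 of 41 with 1 fall, the same counts adjusted over the list alone (median log2 2.53; camera adjusted p = 2.81e-05, and adjusted p = 0.988 with an estimated correlation). Ckm, the muscle creatine kinase, was 113-fold higher, from 71.0 ± 26.2 (n = 2) to 9618 ± 1102 (n = 3), and Myh8, the perinatal myosin heavy chain, 26.0-fold higher. The gene that fell was Myf5, an early myogenic factor.

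Among the stage genes, Krt5 (2.63-fold), Krt14 (3.26-fold), Krt10 (2.41-fold), Krt1 (1.49-fold), Grhl3 (7.45-fold) and Klf4 (2.69-fold) were higher at E16.5. Krt10 gave the highest signal of all probesets on each E16.5 array, so its fold is a lower limit if that signal was saturated. Median centring ended the calls of Krt10 (adjusted p = 0.0999), Klf4 (adjusted p = 0.119) and Lor (adjusted p = 0.113) and turned the log2 change of Krt1 from 0.57 ± 0.18 (SE) to −0.38 (adjusted p = 0.101). The Krt1 call was also lost without E14.5 replicate 1 (0.25, adjusted p = 0.218) and without a variance trend (adjusted p = 0.0536). Lor, which encodes loricrin, rose by 1.30 ± 0.16 on its brightest probeset and changed by −1.41 with the mean of its 3 probesets. Trp63 fell by 1.27 ± 0.18 on the log2 scale on its brightest probeset, while the other 3 of its 4 probesets rose, and the mean of all gave 2.49. Krt8 and Krt18, keratins of simple epithelia, were 9.73-fold and 22.2-fold lower at E16.5. Their E14.5 signals were 6892 and 1745 for Krt8 and 5947 and 791 for Krt18 in replicates 1 and 2. Their log2 changes of −3.28 and −4.48 were −2.30 and −3.03 without E14.5 replicate 1, and −4.27 and −5.92 without replicate 2.

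The largest falls were Afp, which encodes alpha-fetoprotein (at least 35.9-fold; log2 −6.30 ± 1.61 SE, n = 2 and 3, adjusted p = 0.0064), Map3k12 (78.3-fold), Zfp317 (at least 65.9-fold), Rai2 (at least 53.2-fold) and Zbtb38 (at least 36.0-fold). Afp signals were 29660 and 132 in E14.5 replicates 1 and 2, and its log2 change was −2.47 without replicate 1 and −10.12 without replicate 2. Of the 3 probesets of Zbtb38, 1 was called lower and 0 higher, and of the 4 of Map3k12, 3 lower and 0 higher.

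limma called 10526 of 18193 genes (57.9%) between E14.5 and E16.5, 6744 higher and 3782 lower at E16.5. The share that rose was 64.1%, 50.6% under quantile normalization and 28.5% under median centring, which moved the median log2 change of all genes from 0.30 to −0.03 and −0.66. In 2540 of the 5068 genes with at least 2 called probesets, the probesets were called in opposite directions. Pairs of called probesets of 1 gene went the same way in 59.5% of cases. The share expected if called probesets moved independently, computed from the share of them that rose, was 56.1%. Such pairs went the same way in 10 of 10 cases for the skeletal muscle list, 5 of 6 for cornified envelope, 33 of 40 for lipid barrier, 5 of 7 for proteases and 29 of 54 for basal keratinocyte genes. Within these lists, where most called probesets rose, the share expected in the same way was 95.5%, 95.7%, 80.6%, 88.9% and 70.3%. The shares of the last 2 lists and of cornified envelope genes lay below it. Among genes with 2 or more probesets of 1 sign, camera called 1 list, ribosomal protein genes, which were lower at E16.5 (median −0.39, adjusted p = 0.00109). The cornified envelope (7 genes, adjusted p = 0.168), skeletal muscle (adjusted p = 0.168), basal keratinocyte (adjusted p = 0.34) and lipid barrier (adjusted p = 0.365) lists were not called there, with medians of 3.05, 3.10, 1.65 and 1.40 that were no smaller than among all their genes, and the proteases had too few such genes.

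Over the whole course, from E14.5 to E18.5, the 5 largest rises were Lce1c (at least 241-fold), Lce1i (at least 233-fold), Lce1f (at least 193-fold), Lce1a1 (at least 175-fold) and Lce1d (at least 157-fold), with SEs of 0.29 to 0.48 on the log2 scale (n = 2 and 3). Hbb-y was at least 122-fold lower (log2 −7.47 ± 0.72 SE, adjusted p = 8.08e-06), Rpf2 at least 105-fold and Rpl27a 70.2-fold lower, Afp at least 22.4-fold and Lce3f at least 20.7-fold lower. Without E14.5 replicates 1 and 2 in turn, the log2 change of Afp (−6.27) was −2.45 and −10.10 and that of Lce3f (−5.84) was −6.84 and −4.84. Of the 4 probesets of Rpf2, 2 were called lower and 1 higher.

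The lists called from E14.5 to E18.5 were basal keratinocyte, cornified envelope and granular layer, proteases and inhibitors, skeletal muscle, hair shaft and inner root sheath, and adipocyte, all higher at E18.5. In that order 14 of 19, 35 of 45, 26 of 31, 31 of 41, 26 of 34 and 23 of 27 genes rose and 2, 3, 1, 3, 1 and 2 fell, with the same counts adjusted over the list alone. Median log2 changes were 2.01, 3.24, 2.12, 2.75, 2.38 and 2.37 against 0.51 for all genes. Camera gave adjusted p = 0.0074, 2.13e-05, 0.000442, 0.000281, 0.00412 and 0.000721, and each list had adjusted p = 0.842 with an estimated correlation. limma called 11129 genes, 7585 higher and 3544 lower. The share that rose was 68.2%, 51.5% under quantile normalization and 28.3% under median centring, with median log2 changes of all genes of 0.51, 0.01 and −0.56. Probesets were called in opposite directions in 2406 of 5148 genes.

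Across both intervals, 1666 genes were called in each. Krt79, a keratin, rose in both (at least 21.6-fold, then log2 2.62 ± 0.27 SE), as did Car3 and Sprr2h. At E16.5, 2 of the 4 probesets of Car3 were called higher and 1 lower. Krtap13, Saa1 and Krt77 rose and then fell. Tchh fell at least 16.6-fold and then rose at least 26.6-fold, with signals of 1064, 48.2 and 2110 at the 3 stages, as did Psmc4 and Ddr1. For Psmc4, 1 of 2 probesets was called lower at E16.5 and 0 higher. The other gave 2191 and 2552 at E14.5, 2395 to 2402 at E16.5 and 2465 to 3353 at E18.5. Of the 8 probesets of Ddr1, 3 were called higher and 3 lower at E16.5, and its first fall was not called with their mean or median (limma adjusted p = 0.108 and 0.843). From E16.5 to E18.5 the probesets of Ddr1 did not all rise either. Hbb-y, Gsta4 and Acsf2 fell in both, with the first log2 change of Hbb-y (−5.12) at −5.83 and −4.45 without E16.5 replicates 1 and 2 and its second call lost without several arrays. The second change of Tchh was 5.35 without E18.5 replicate 3.

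By pattern, 312 genes rose in both intervals, 618 rose and then fell, 524 fell and then rose, and 212 fell in both. Independent lists of the same sizes would share 491, 376, 275 and 211 genes. Simulated arrays without any effect gave 0 for each, but without an effect hardly any gene is called in either interval. That 0 is therefore no chance level for the genes shared by these calls. Both changes use the same E16.5 arrays, so part of the excess of opposite changes may come from them. The log2 changes of the 2 intervals correlated across genes with r = −0.22 (−0.45 in the simulation), with a covariance of −0.20 (−0.05 in the simulation); genes are not independent replicates. Without E16.5 replicates 1, 2 and 3 in turn, 717, 705 and 538 genes were called in both intervals.

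The change differed between the intervals for 8225 genes by limma's contrast, with the second change the higher in 3208 and the lower in 5017. By the measured signals, Krtap13 (log2 difference −15.36 ± 0.81 SE), Il1f9, an interleukin of the IL-1 family (−10.17 ± 0.44), and Klk7 (−9.07 ± 0.39) had the largest negative differences, and Tchh (8.84 ± 0.82), Krt25 (8.03 ± 0.95) and Zbtb38 (7.57 ± 0.46) the largest positive ones. Each had signals at or below background at 1 or more stages, and the values nearest 0 that such signals allow are −12.66, −9.09, −7.48, 8.78, 4.60 and 5.62 in the same order. Without 1 array, Krtap13 ranged to −14.48 and −16.36 (E16.5 replicates 1 and 2), Krt25 to 8.67, 7.39 and 8.62 (E14.5 replicates 1 and 2, E18.5 replicate 3) and Tchh to 9.43 (E18.5 replicate 3). The share with the higher second change was 39.0%, and 69.2% under median centring. The F test over the 3 stages called 11799 genes (64.9%).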

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

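The tests of the E14.5 array preparation, of scaling by the number of genes called and of the keratinocyte share were chosen after their results were seen, and the margins for the direction of calls under scaling (2 SE) and for periderm (3 SE) were also set after the values were known.

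The change over the second interval minus that over the first was set apart by camera for 8 gene lists, each in data where the E14.5 arrays differ from the later ones in their control probesets. The median log2 difference was −3.92 for cornified envelope and granular layer genes, −2.30 for skeletal muscle, −2.22 for epidermal proteases and inhibitors, −2.11 for the epidermal lipid barrier, −1.45 for basal keratinocyte genes and −1.40 for mast cell genes. It was 1.58 for hair shaft and inner root sheath genes and 0.42 for ribosomal protein genes. No list was called with an estimated correlation (adjusted p of 0.926 or more).

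Control probesets, which enter none of the comparisons, gave other signals on the E14.5 arrays than on the other 6. On the log2 scale E14.5 was higher by 2.44 in the beta-actin 3′ over 5′ ratio, by 1.89 in that of Gapdh, by 3.22 in bioB and by 5.83 in the middle probeset of 18S ribosomal RNA.

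Most genes were called between E14.5 and E16.5. If the change were of whole transcripts, called probesets of 1 gene would mostly move together, but only 59.5% of such pairs went the same way, which is consistent with a difference in target preparation between the E14.5 arrays and the rest, as a hypothesis found on these data. Scaling as the whole cause is argued against, since quantile normalization called 93.2% as many genes and median centring 108% (90.0% to 109% without any 1 array), but its part in the direction of single calls stays open, with 77.2% and 66.9% of the calls kept, the latter above the bound set in advance by less than 2 SE. For the cornified envelope genes the preparation cannot be told apart from stage. There 83.3% of 6 pairs went the same way, against 95.7% expected if called probesets of the list moved independently. Among the 7 genes with agreeing probesets the median stayed at 3.05, and camera did not call the list (adjusted p = 0.168). Why the call was lost there was not tested. A real difference between the stages stays open for every gene.

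E14.5 replicate 1 carried liver-type transcripts. A list of liver genes, 24 of them measured, was written after Afp, Ttr and Serpina1b had been seen and leaves these out. It was higher there than in replicate 2 by a median log2 of 5.28, in 24 of 24 genes, with Apoa4 at 17490 against 30.8 and Alb at 7351 against 23.7, so liver or yolk sac tissue in the sample is a candidate explanation, although skin also gave signal for some members, up to 1064 for Rbp4 at the later stages. More periderm would raise its genes alike, but the other 15 differed by a median of 0.17 against 1.97 for Krt8 and 2.89 for Krt18. The SE of that median, 0.41, comes from resampling genes and treats them as independent. Krt4 differed by −0.38 and Krt19 by −0.06. Krt20 (5.07), Cldn7 (3.58) and Cldn6 (signals of 1518 and 67.6) were higher in replicate 1, so a source for these stays open. Both arrays share 1 label, so the design gives no biological explanation, and none was tested beyond these 2 tissue sources.

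Of 36 epidermal lipid barrier genes, 13 fell and 3 rose between E16.5 and E18.5, and camera set the list below other genes. A lower share of keratinocytes would lower basal and spinous genes alike, but the median of these 37 genes lay 0.69 (SE 0.21) above the lipid barrier median. That SE comes from resampling genes. It treats genes as independent and leaves out the spread between arrays, so it may be too small. For the list's place below other genes, array scaling is argued against by the camera call, which held under quantile normalization (adjusted p = 4.51e-07). The list also kept its call in all 22 alternatives run at the preset correlation. Camera compares the list with other genes, so these calls do not test whether scaling changed the falls of single genes. A change in the differentiated layers with stage and a difference in array handling between these stages stay open and were not tested, as does chance correlation among the list's genes, since adjusted p = 0.618 with an estimated correlation.

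Other splits of the samples were counted. For E18.5 against E16.5, 1 of 10 splits of the 6 arrays, the real one, gave as many as 2340 genes, and the highest other split gave 1. For the lists, 3 of the 10 splits gave 16 or more called lists and the highest other gave 19. The number of called lists was therefore no larger than splits that mix the stages can give. With 10 splits no share under 0.05 is possible. For the F test, 1 of 100 splits, the real one, gave as many as 11799 genes, a share under 0.05. The highest other split gave 9117, and it kept both E14.5 arrays together. Splits that parted them gave at most 3, which points to the distance of the E14.5 arrays from the rest. The F count therefore cannot exclude chance in how the E16.5 and E18.5 arrays were grouped, nor separate stage from preparation at E14.5.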

How the results depend on the processing

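The variants with the median of all probesets and with agreeing probesets were chosen after the data were seen; the others were planned before the data were examined. Named genes kept direction and call in every alternative for 35 of 41 genes from E14.5 to E16.5, 33 of 52 from E16.5 to E18.5, 10 of 10 from E14.5 to E18.5 and 6 of 6 of the unequal changes. Of the genes called from E16.5 to E18.5, 15 lost their call without at least 1 array. No called list kept its call with the estimated correlation. At the preset correlation, called lists kept their call in every alternative that left at least 5 of their genes for 1 of 5, 3 of 16 and 2 of 6 lists in the same order of comparisons; the 3 from E16.5 to E18.5 were adipocyte, epidermal lipid barrier and hair shaft and inner root sheath, of which fry did not call the lipid barrier (adjusted p = 0.106). The numbers of called genes from E14.5 to E16.5 and of unequal changes stayed within 1.5 times under every setting chosen beforehand. From E16.5 to E18.5 the count was 758 to 2624 over fits without 1 array, and 930 at a fold of at least 2; genes called in both intervals ranged from 538 to 1866, and those in opposite directions, 1142 in all, from 380 to 1205. The low counts came without an E16.5 array; without E18.5 replicates 1, 2 and 3 the count was 1966, 1919 and 2551, so the number of samples alone does not account for them. Only genes above the median gene gave 7277 genes for E18.5 against E14.5 and 7749 for the F test, with fewer genes tested. Genes with 2 or more probesets all called in 1 direction numbered 1447, 119 and 1588 (E16.5 against E14.5, E18.5 against E16.5, E18.5 against E14.5), with fewer genes tested. For lists in that order of comparisons (5, 16 and 6), the estimated correlation gave 0, 0 and 0, fry 21, 9 and 24, and agreeing probesets 1, 5 and 0. The 9 that fry called from E16.5 to E18.5 were all higher at E18.5 (fry adjusted p = 0.00522 to 0.0383). They were the hair shaft, follicle signalling, keratin-associated, adipocyte, melanocyte, macrophage, ribosomal, dermal papilla and Merkel cell lists. Quantile normalization gave 10 lists for E16.5 against E14.5, and for E18.5 against E16.5 genes above the median gene gave 7 lists and genes above background on 2 arrays 10. Signs turned for Krt1 (−0.38, median centring), Lor (−1.41, mean of probesets) and Trp63 (2.49 with the mean and 3.45 with the median of probesets), all E16.5 against E14.5. From E16.5 to E18.5, the immediate early and heat shock list was called lower (−0.20, adjusted p = 0.0172) without E18.5 replicate 2, in a range of −0.20 to 0.46 over fits without 1 array, and camera pointed down, with no call (adjusted p = 0.722), for the keratin-associated list among agreeing probesets, whose median was 0.29 in 5 genes. The cause was not tested. Without 1 E14.5 array, the lone array left is assumed to vary like the other stages. Replicate numbers pair no arrays. Signals near background, which was higher at E18.5 (log2 6.55 against 5.87 at E16.5), limit small changes of dim genes.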

Other observations

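Several lists did not pass camera from E16.5 to E18.5. In the dermal papilla and condensate list 6 of 24 genes rose and 2 fell (median log2 0.36, adjusted p = 0.236), in the cartilage and bone list 3 of 24 rose and 0 fell (0.39, adjusted p = 0.33), and in skeletal muscle 8 of 41 rose and 5 fell (0.22, adjusted p = 0.616). Basal keratinocyte genes had 2 rises and 1 fall among 19 (0.02, adjusted p = 0.96), spinous keratinocyte genes 3 and 3 among 18 (0.10, adjusted p = 0.788) and epidermal transcription factors 5 and 8 among 30 (−0.19, adjusted p = 0.088). Desmosome (3 and 3 of 15, adjusted p = 0.788), tight junction (4 and 3 of 19, 0.33), innate defence (2 and 3 of 21, 0.616), collagen (6 and 1 of 42, 0.323), Hox (1 and 1 of 33, 0.788), S100 (3 and 1 of 15, 0.236), Merkel cell (1 and 0 of 16, 0.532), Schwann cell and nerve (1 and 2 of 23, 0.0954), endothelium (1 and 2 of 25, 0.175), T cell (1 and 2 of 19, 0.934) and immediate early and heat shock genes (1 and 0 of 24, 0.785) were not called either. Median, mean and test differed in sign for spinous keratinocyte genes (mean −0.22, test down), desmosome genes (median −0.02, mean 0.09, test down), innate defence (median 0.03, mean 0.03, test down) and T cell genes (median 0.27, mean 0.14, test down). Camera's direction is relative to the other genes, and the median of all genes was 0.12. A list with a small positive change can therefore test down, so the difference in sign is no conflict in itself. The counts are genes that rose and fell, followed by camera's adjusted p. By fry, the dermal papilla and condensate list (adjusted p = 0.0332) and the Merkel cell list (adjusted p = 0.0327) were called higher at E18.5.

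Xist, expressed from the inactive X chromosome of females, gave signals of 10700 in E14.5 replicate 1, 11112 and 11736 in E16.5 replicates 1 and 3 and 13611 in E18.5 replicate 2. It gave 26.1 to 202 on the other 4 arrays. The Y-linked gene Eif2s3y gave 364.6 to 3241 on those 4 arrays and in E14.5 replicate 1, and 1.76 to 15.8 on the other 3 arrays. E14.5 replicate 1, which also carried the liver-type transcripts, was thus the only array with high signals of both genes, with Eif2s3y at 364.6. The source of both signals on that array was not tested.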
